A study of Mus musculus with 18 samples.

How the data were processed

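RNA of lumbar spinal motor neurons was measured on 18 one-colour oligonucleotide arrays, 1 per mouse. Per the labels' protocols, 1000 motor neurons per animal were captured by laser from 10 µm sections stained with toluidine blue, and their RNA was extracted, amplified and labelled with biotin. The mice carried the human SOD1 G93A transgene or were non-transgenic littermates, called controls here, and were 60, 90 or 120 days old, with 3 animals in each of 6 groups. The groups were taken from the sample labels.

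The deposited values are the authors' signal intensity per probe set on a linear scale, made with MAS5 per the submitters' processing notes, and the software version and settings are not given in the sources used here. The values were checked to be scaled per array, with a mean of about 100 on each of the 18 arrays once the highest and lowest 2% were trimmed. Detection calls were not used here. The table holds 22690 probe sets, of which 64 are control probe sets. Of the others, 20380 carry 1 gene symbol, 691 carry several and 1555 carry none in the platform annotation used here. Through the Entrez identifier, 20351 of the 20380 were matched to a table of mouse genes of the assembly GRCm38.p6, and 0 symbols needed an update. Genes are named only from probe sets with 1 symbol, and no coordinates are given.

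The signals were put on the log2 scale after values under 1 were set to 1, which applied to 965 of 408420 values (0.236%). No further normalization was applied. A probe set was tested if its signal lay above its array's median in at least 3 of the 18 arrays, and control probe sets were left out, which kept 16565 probe sets. Differences were estimated with limma 3.58.1 in R 4.3.3: a linear model of the 6 group means over all 18 arrays, contrasts, and empirical Bayes moderation with a trend in the mean level. The fit left 12 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 16565 probe sets within each comparison, and an adjusted p below 0.05 counted as a change. All limma tests were two-sided. Errors given with ± are standard errors of the log2 difference from this fit, and n is 3 animals per group unless stated.

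The comparisons were G93A minus control at each of the 3 ages, the mean of the 3 differences (9 G93A animals against 9 controls, with age held fixed), the change of the genotype difference with age (an F test of the differences at 90 and 120 days against that at 60 days), and 120 minus 60 days within controls and within G93A animals. For gene lists and for naming, a gene was represented by its tested probe set of highest mean level, with probe sets marked as cross-hybridizing (suffix _x_at) used only where no other was tested. This gave 10051 genes. For each genotype comparison 32 gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists. The same test with a correlation estimated per list, and fry, were run beside it. Camera compares a list with the other genes, while fry tests a list against no change, so they answer different questions. A list's value is the median log2 difference of its measured members. The list level of an array is the mean log2 level of the members minus the mean over all genes. Some lists share genes, for example subunits of succinate dehydrogenase in the oxidative phosphorylation and TCA cycle lists.

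The genes named in the text followed a rule. For each genotype comparison at an age, up to 10 genes per direction with the largest change were taken among those past the threshold with no overlap between the 3 G93A and the 3 control arrays. Where fewer passed, the list was filled to 10 with genes of the smallest unadjusted p among those with at least a 1.5-fold difference and no overlap, and these are given as values and not as changes. For other comparisons the limit was 5 per direction. Of each gene list, up to 4 members of the smallest p were eligible. Sod1, Prph, Nefl, Gfap, Aif1 and Mbp were always included. Chat was not analysed here. Where other probe sets of a named gene differed in sign, the text says so. Further genes named beside the rule were chosen after their values were seen: Lgals3, Gfap and Mbp among the age comparisons, Lyz1 in the mean over ages, and the fifth and later members of a list. The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined.

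Array quality was read from correlations between arrays over the tested probe sets and from control probe sets: the mean log2 level of the 12 hybridization-control probe sets, the log2 ratio of the 3' to the 5' Gapdh probe set, the 18S rRNA level and the level of the poly-A controls. Group differences in these were tested with an exact permutation test, two-sided, which with 3 against 3 cannot go below 0.1. For the lists at 120 days the level per array was also modelled on the 6 groups and an array measure by ordinary least squares over the 18 arrays. The measure was the hybridization-control level or the log2 median signal, each read after the scaling per array. The test scripts were tested on simulated data made from these arrays. The number of arrays limits the precision of each difference.

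Alternatives tried were quantile normalization, centring each array on its median, no filter, a stricter filter (the upper 40% of probe sets by mean level), a pseudocount of 15.35 (the median over arrays of the 25th percentile) added before the logarithm, moderation without the trend, array weights, the sample number as a block, the animal number series at 90 days as a block, a fit with only the arrays of the ages compared, the mean over a gene's probe sets, and leaving out each array in turn. A covariate for the hybridization-control level, a covariate for the Gapdh ratio, and a fit without the least correlated array of each age were chosen after seeing the data.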

Results

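Gene expression was measured in motor neurons captured by laser from the lumbar spinal cord of mice that carry the human SOD1 G93A transgene, a model of inherited amyotrophic lateral sclerosis, and of their non-transgenic littermates. The animals were 60, 90 or 120 days old, and each of the 6 groups held 3 animals with 1 array each. The comparisons ask which motor neuron transcripts differed between the genotypes at each age, and whether the difference changed with age. Signals of 16565 probe sets were tested, and the number of arrays limited the precision: the median standard error of a genotype difference at 1 age was 0.69 on the log2 scale. In data simulated for the comparison at 120 days, a log2 change of 1 was recovered for 0 of 50 changed probe sets, a change of 2 for 30 of 50 (60%), a change of 3 for 43 of 50 (86%) and a change of 4 for 50 of 50 (100%). The changed probe sets were drawn only from those above the median in mean level, and the noise was independent between probe sets. The simulated data held many more calls than the 4 of the real comparison at 120 days, which loosens the adjustment. Recovery in the real comparison can therefore be lower than these shares. Recovery among probe sets of low signal was not simulated.

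Arrays of the same group correlated at 0.641 to 0.838 across probe sets, with a median of 0.742 over 18 pairs. Arrays of different groups correlated at 0.539 to 0.864, with a median of 0.685 over 135 pairs. These are correlations across genes, which are not independent replicates. The level of the hybridization controls, added to every array, was lower on the G93A arrays at 60 days (mean log2 10.35 against 12.02 in controls, no overlap, exact permutation p = 0.1, n = 3 against 3). It was 10.17 against 10.92 at 90 days (exact permutation p = 0.4) and 12.62 against 12.63 at 120 days (exact permutation p = 1). The ratio of the 3' to the 5' Gapdh probe set was higher in G93A at 60 days, 4.14 against 3.36 on the log2 scale (exact permutation p = 0.1, the smallest that 3 against 3 allows). It was 4.39 against 3.25 at 90 days (exact permutation p = 0.2) and 4.94 against 4.48 at 120 days (exact permutation p = 0.3). The same ratio for beta-actin, on the linear scale, was 41.9, 38.6 and 27.6 in G93A and 29.5, 74 and 215 in controls at 60 days. It thus did not share the Gapdh difference at that age, and 3' bias is read here from Gapdh alone. The median signal was 54.3 in G93A and 43.7 in controls at 120 days (exact permutation p = 0.1), 52.8 and 61.5 at 60 days (exact permutation p = 0.2), and 47.4 and 52.9 at 90 days (exact permutation p = 0.4).

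**Figure D1:**
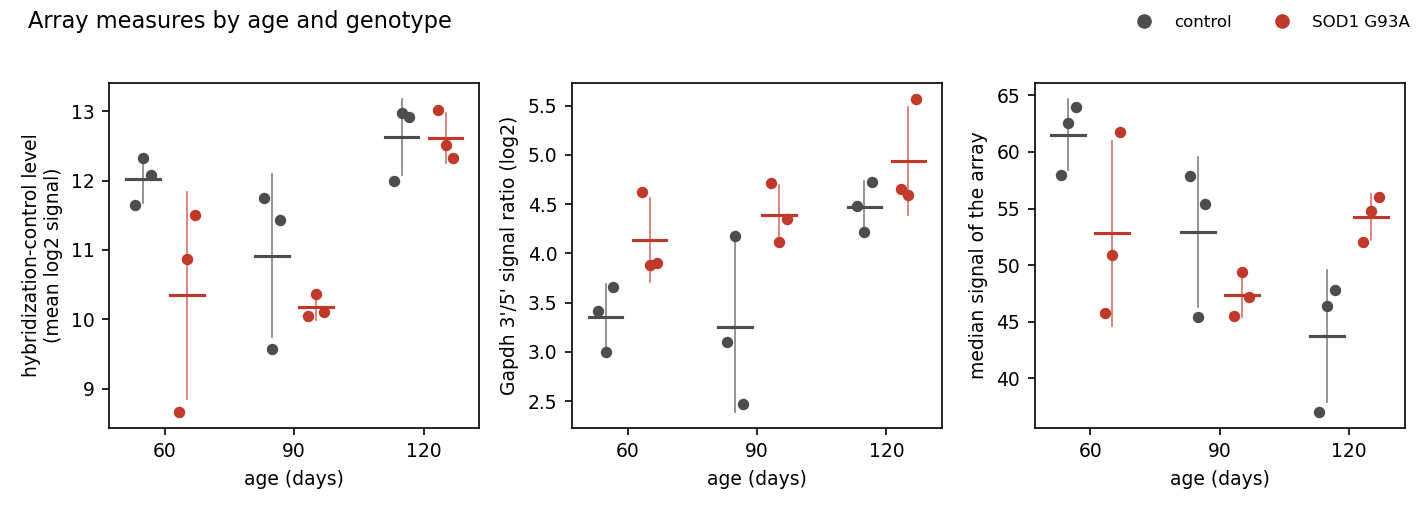
Level of the hybridization controls (log2), log2 ratio of the 3' to the 5' Gapdh probe set, and median signal of each array by age in days and genotype; points are arrays, bars are group means and thin lines 1 SD either way. At 60 days the hybridization-control level averaged 10.35 in G93A and 12.02 in controls, without overlap.

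Of the 2 tested probe sets for the mouse Sod1 gene, 0 passed the test at any age. The transgene is of human sequence, and whether these probe sets detect its RNA is not given in the sources used here. The log2 difference of the probe set that represents Sod1, G93A minus control, was 0.75 ± 0.56 at 60 days, 1.18 ± 0.56 at 90 days and 0.05 ± 0.56 at 120 days (limma adjusted p = 0.626, 0.997 and 0.986). At 120 days control replicate 1 had a signal of 1576.9, against 134.2 and 213.4 in the other controls, and without it the difference was 1.12. The second Sod1 probe set differed by 1.08 ± 0.43 at 60 days without overlap (limma adjusted p = 0.279), by 0.58 ± 0.43 at 90 days and by 0.33 ± 0.43 at 120 days. Of the cell type genes always reported, Nefl, the light neurofilament chain, differed by -0.89, -0.67 and -0.65 at 60, 90 and 120 days. Its standard error was 0.48 at each age. Under quantile normalization the Nefl value at 60 days was 0, without G93A replicate 1 of 60 days it was -0.43, and without control replicate 2 of 120 days that at 120 days was -0.32. Mbp of myelin differed by 0.26, 0.28 and -0.02 (± 0.38), and Prph, the neuronal intermediate filament peripherin, by -0.09, 0.14 and -0.95 (± 0.42). These values of Mbp, and those of Prph at 60 and 90 days, changed sign with 1 array left out or under centring, except that of Mbp at 60 days. The Prph value at 120 days was -0.38 without control replicate 1, whose signal was 590.4 against 175.9 and 180.5 in the other controls. Gfap, the intermediate filament of astrocytes, differed by -0.63, 0.73 and 2.25 (± 0.57), and its mean log2 level at 120 days was 9.04 in G93A and 6.79 in controls. The Gfap value at 60 days was 0.02 without G93A replicate 2 of that age and -1.01 without G93A replicate 3, and that at 90 days was 0.2 without control replicate 1. None of these passed the adjustment at an age. Aif1 was not tested, since it lay above the array median in 1 of 18 arrays, with signals from 3.9 to 85.9.

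**Figure D2:**
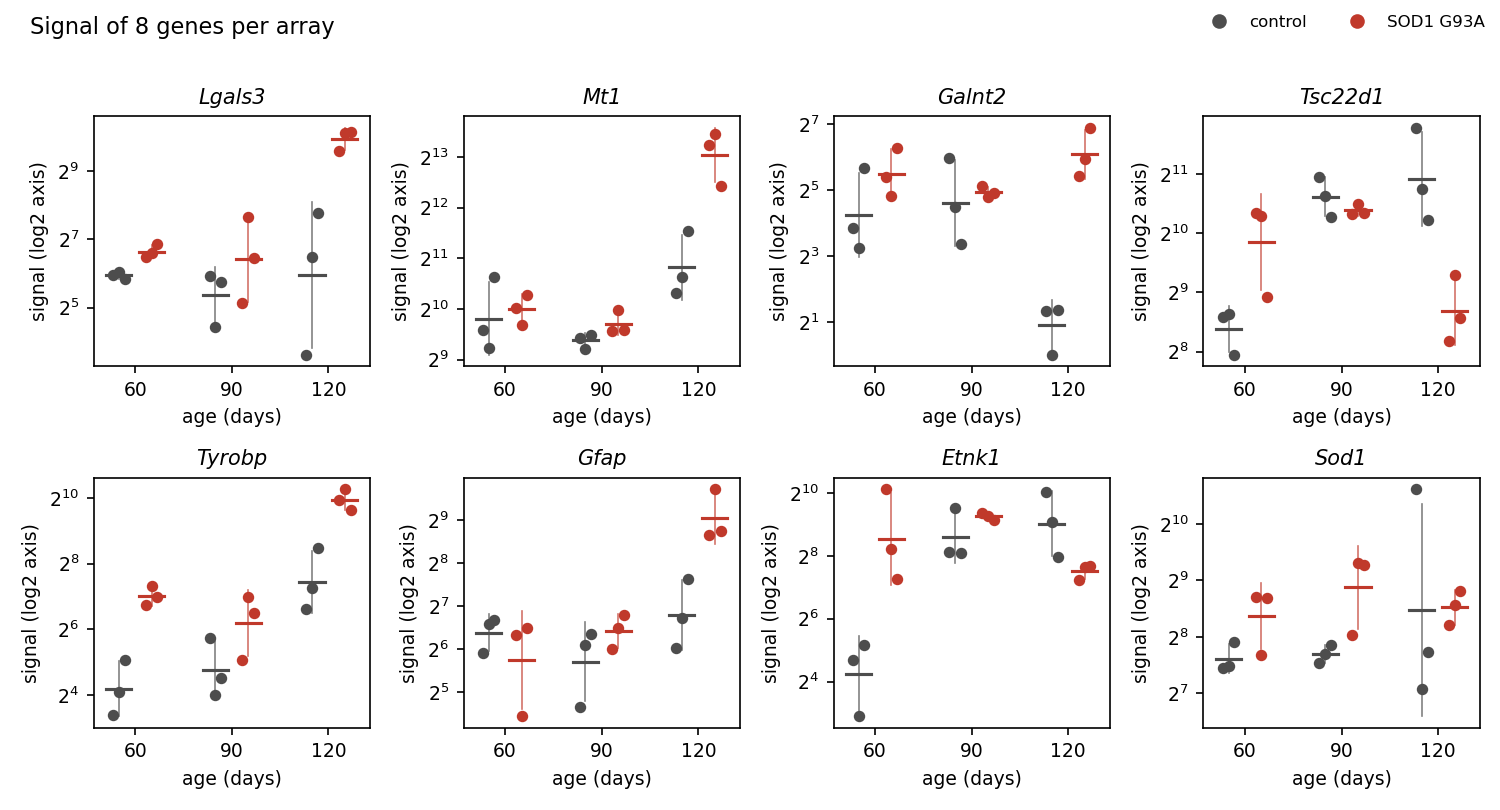
Signal of Lgals3, Mt1, Galnt2, Tsc22d1, Tyrobp, Gfap, Etnk1 and Sod1 on each array by age in days and genotype, on a log2 axis; points are arrays, bars are geometric means and thin lines 1 SD of the log2 values either way. At 120 days the G93A signals of Lgals3 lie between 768.2 and 1135.5 and the control signals between 12.2 and 218.2.

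At 60 days, before the age at which motor neurons are lost in large numbers in this model, 114 probe sets of 93 genes changed, 111 higher and 3 lower in G93A. Etnk1, which encodes ethanolamine kinase, rose by 4.28 ± 0.61 on the log2 scale (limma adjusted p = 0.00216), and Id2, a repressor of basic helix-loop-helix factors, by 3.77 ± 0.56 (limma adjusted p = 0.00251). Ptch1, the receptor of hedgehog ligands, rose by 3.91 ± 0.67 and Tceal1 by 3.62 ± 0.63 (limma adjusted p = 0.00674 for each). The actin regulator Enah rose by 3.82 ± 0.72 (limma adjusted p = 0.0148). Dcun1d5 (4.36), Atp6v1b2 (4.07), Phkb (3.81), Marcks (3.37) and Ddx5 (3.35) rose with adjusted p from 0.00674 to 0.0372. Control signals of 60 days behind these values were low, such as 25.9, 7.4 and 36.2 for Etnk1, 7, 42.6 and 8.2 for Id2, 2.4, 8 and 2.1 for Dcun1d5, and 3.9, 10.6 and 7.5 for Atp6v1b2, so that the sizes and their order depend on the treatment of low signals. With a pseudocount of 15.35 the differences were 3.42 for Etnk1, 3.28 for Enah, 3.00 for Ptch1, 2.68 for Id2, 2.60 for Atp6v1b2, 2.45 for Ddx5, 2.37 for Tceal1 and 2.16 for Dcun1d5, and the calls of Marcks (2.21) and Phkb (1.98) were lost. Of the 114 calls 97 were kept with it, and in 23 the geometric mean of the lower group was below that pseudocount. Other tested probe sets went the opposite way for Etnk1 (2 of 2), Dcun1d5, Atp6v1b2 and Id2 (1 of 1 each), Marcks (1 of 5) and Ddx5 (2 of 5). Batf3 fell by 3.20 ± 0.76, Cndp2 by 1.53 ± 0.34 and C2cd2l by 1.25 ± 0.30 (limma adjusted p = 0.0469, 0.0335 and 0.0479). Without passing the test, Slc6a5 had a log2 difference of -2.58, Hbb-b2 of -2.44, Mark4 of -1.58, Idh3g of -1.32, Lin7b and Klhdc3 of -1.28, and Bscl2 of -1.25.

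The 114 probe sets called at 60 days were low in the controls of that age and not in the controls of the other ages. Their median log2 level was 5.83 in controls and 8.28 in G93A at 60 days, 8.07 and 8.35 at 90 days, and 8.08 and 7.39 at 120 days. The other 16451 tested probe sets had medians of 6.26 and 6.15 at 60 days. Of the 114, 97 had a difference of the same sign at 90 days, 12 at 120 days, and 0 were called at 120 days. The G93A arrays at 60 days were also those with the lower hybridization-control level (a difference of -1.67), and with that level in the model 1 probe set was called in place of 114. The median difference of the 111 higher ones went from 2.43 (SE 0.48) to 1.81 (SE 0.54) in that model. Leaving out 1 array gave 7 calls without G93A replicate 1 of 60 days, 29 without G93A replicate 2, 45 without control replicate 3, 267 without control replicate 1 of 60 days, and 173 without control replicate 1 of 120 days.

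Of the 32 gene lists, 3 shifted upward at 60 days by camera: oligodendrocyte markers with a median log2 difference of 0.51 (adjusted p = 0.049), splicing and hnRNP proteins with 0.24 (adjusted p = 0.035), and heat shock proteins and chaperones with 0.42 (adjusted p = 0.035). None of these calls held with an estimated correlation (adjusted p = 0.751 with an estimated correlation for each). Of the splicing list, 1 member rose over all genes and 6 rose when adjusted over the list alone. With the hybridization-control level or the Gapdh ratio in the model 0 lists were called at 60 days. The medians were then 0.11 and 0.17 for the chaperones, 0.2 and 0.22 for the oligodendrocyte markers, and 0.23 and 0.36 for splicing. Without control replicate 3 of 60 days the splicing median was 0.06 and that of the chaperones 0.2, and without G93A replicate 1 of 60 days the chaperones had 0.25 and the oligodendrocyte markers 0.33, with these 4 calls lost. Members of the splicing list include Sf3b1 (2.38 ± 0.54), Hnrnpa2b1 (1.83 ± 0.49), Mbnl1 (1.41) and Srsf3 (1.47). Of the oligodendrocyte markers, Ugt8a (1.99 ± 0.55) rose when adjusted over the list alone and 0 over all genes. Of the chaperones, 0 passed when adjusted over the list alone or over all genes, with 12 higher at an unadjusted p below 0.05, among them Hspa9 (1.38 ± 0.40) and Cct5 (1.33 ± 0.41). Members of other lists that rose over all genes were Tyrobp (2.81 ± 0.58), Dlst (3.20 ± 0.66), Mdh1 (2.20 ± 0.51), Dlat (1.33 ± 0.32), Eef1b2 (2.06 ± 0.36), Dhcr7 (2.43 ± 0.52), Atp5c1 (1.87 ± 0.44) and Atp6v1b2 of the synaptic vesicle list (4.07). Without G93A replicate 1 of 60 days or G93A replicate 3 of 120 days 0 lists were called, and without G93A replicate 3 of 60 days 5 were. The other 29 lists had adjusted p from 0.066 to 0.94 and medians from -0.76 for S to M cell cycle genes to 0.34 for the TCA cycle. The median of all genes was -0.06 at 60 days, 0 at 90 days and 0.07 at 120 days, and became 0.15, 0.12 and -0.19 once each array was centred on its own median, so directions close to 0 depend on the scaling.

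**Figure D3:**
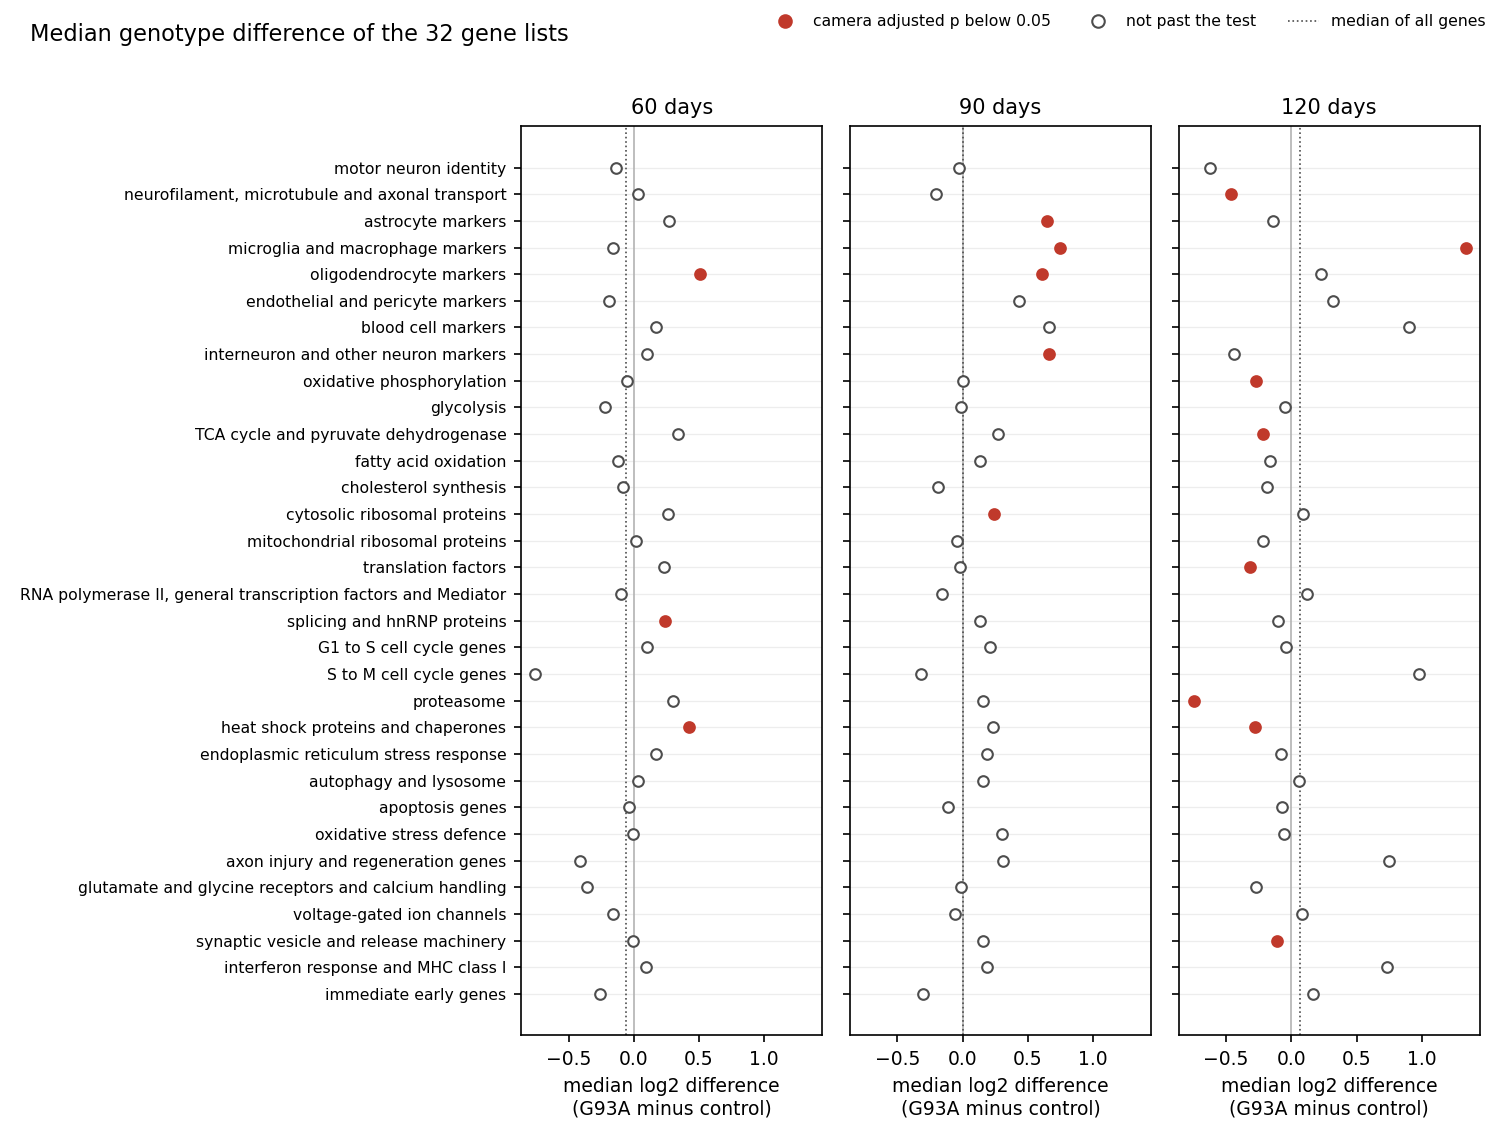
Median log2 difference, G93A minus control, of the members of each of the 32 gene lists at 60, 90 and 120 days; filled red points are lists with a camera adjusted p below 0.05 and the dotted line is the median of all genes. Microglia and macrophage markers stand at 0.75 at 90 days and 1.34 at 120 days, and the proteasome list at -0.75 at 120 days.

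At 90 days no gene passed the test, and 5 lists shifted upward by camera at the preset correlation: the microglial, astrocytic, oligodendrocyte, interneuron and ribosomal ones. By limma 0 of 16565 probe sets changed, with 756 at an unadjusted p below 0.05 (380 higher, 376 lower) where 828 are expected by chance. Among genes without overlap, the 10 positive values of the smallest p were, by size, those of Mndal (3.56 ± 0.84), Fxyd3 (3.19 ± 0.88), Rnf8 (2.59) and Zmiz2 (2.54), and those of Wdr55, Golga7, Pum2, Cst3, Rpl8 and Scd2 from 1.35 to 2.00. The 10 negative values of the smallest p were, by size, those of Mrps5 (-3.76 ± 0.96), St3gal5 (-3.08 ± 0.87), Mrps11 (-3.05 ± 0.72) and D8Ertd738e (-2.81), and those of Cnot3, Rab3b, Ehd3, Cd99l2, Hmga2 and Atg13 from -2.55 to -1.17. Low signals lie behind some of these sizes, and with the pseudocount Mndal had 1.43, Fxyd3 1.69, Mrps5 -1.49 and Mrps11 -2.12. These genes share an adjusted p of 0.795, and chance gives no overlap in 10% of comparisons of 3 against 3. The mitochondrial ribosomal proteins Mrps11 and Mrps5 fell when adjusted over the list alone (limma adjusted p = 0.021 and 0.023) and not over all genes.

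By camera 5 lists shifted upward at 90 days: microglia and macrophage markers (median 0.75, adjusted p = 0.0070), astrocyte markers (0.65, adjusted p = 0.0070), oligodendrocyte markers (0.61, adjusted p = 0.0092), interneuron markers (0.66, adjusted p = 0.040) and cytosolic ribosomal proteins (0.24, adjusted p = 0.040). None held with an estimated correlation (adjusted p = 0.531 with an estimated correlation for the microglial and astrocytic lists and 0.62 for the others), and fry called 0. Of the microglial list 15 of 21 members were above 0, and Ctss (1.22 ± 0.35) rose when adjusted over the list alone and 0 over all genes. Tyrobp (1.43 ± 0.58) and Fcgr3 (1.98) had positive values. The mean level of Fcgr3 lay at percentile 10 of all genes, so its size depends on low signals. The highest astrocytic values were Aqp4 (1.38 ± 0.48), Gjb6 (1.42 ± 0.51) and Fgfr3 (1.80). Mobp (1.96 ± 0.76) of the oligodendrocyte list, Calb1 (1.08 ± 0.41), Sst (2.06 ± 0.82) and Gad1 (1.79) of the interneuron list, and Rpl6 (0.75) of the ribosomal list were positive. The Gapdh ratio was higher by 1.14 in G93A at this age. With it in the model the microglial list alone kept its call (median 0.92), while the astrocyte median was 0.31, the ribosomal 0.01, the oligodendrocyte -0.12 and the interneuron -0.23. With the hybridization-control level in the model the microglial list was also the only 1 of the 5 to keep its call (0.73). The microglial call was lost, and its median was 0.37, without the least correlated arrays and without control replicate 1 of 90 days, and it was lost with 0.49 without G93A replicate 2 of 90 days. The astrocyte median was 0.34 without control replicate 1 of 90 days, and the oligodendrocyte median 0.27 and 0.24 without G93A replicate 3 or control replicate 3 of 90 days, with the calls lost. With 1 array left out the interneuron median went as low as 0.09 (call kept in 11 of 18 fits) and the ribosomal median as low as 0.12 (call kept in 13 of 18). The other 27 lists had adjusted p from 0.15 to 0.95 and medians from -0.32 to 0.66. Lists called numbered 0 without G93A replicate 2 of 90 days, 2 without control replicate 1 or 3 of 90 days, and 3 without G93A replicate 3 of 90 days, G93A replicate 3 of 60 days or control replicate 3 of 60 days.

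At 120 days, an age of advanced disease in this model, Lgals3, Mt1 and Galnt2 rose and Tsc22d1 fell, and these 4 probe sets were all that passed the test of limma, out of 2022 at an unadjusted p below 0.05. Lgals3, the galectin-3 of activated macrophages and microglia, rose by 4.0 ± 0.72 on the log2 scale (16.0-fold, limma adjusted p = 0.0465, n = 3). Its signals were 768.2, 1124.5 and 1135.5 in G93A and 12.2, 89.9 and 218.2 in controls, and with a pseudocount its difference was 3.52. The fold leans on control replicate 1 with 12.2, and the difference was smaller without that array, as given below. The metallothionein Mt1 rose by 2.22 ± 0.36 (4.65-fold, limma adjusted p = 0.0376), with signals from 5527.5 to 11202.4 in G93A and from 1266.9 to 2991.7 in controls. Galnt2, a glycosyltransferase, rose by 5.19 ± 0.94 (limma adjusted p = 0.0465), but its control signals of 2.5, 1 and 2.6 lay at or near the floor of 1. With the pseudocount its difference was 2.28. Tsc22d1, a transcriptional regulator, fell by 2.23 ± 0.39 (4.70-fold, limma adjusted p = 0.0465). Lgals3, Mt1 and Tsc22d1 kept their call in 14, 20 and 18 of 30 alternatives and Galnt2 in 8 of 29, and all 4 kept their direction. The adjusted p ranged from 0.0038 to 0.13 for Lgals3 and Mt1, from 0.007 to 0.17 for Tsc22d1 and from 0.019 to 0.24 for Galnt2.

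Further genes without overlap at 120 days had values that missed the threshold. On the positive side these were Med14 (3.80 ± 0.89), the intermediate filament Vim (2.79 ± 0.60, limma adjusted p = 0.0708), Tyrobp (2.51 ± 0.58), C1qa of complement (2.50 ± 0.48, limma adjusted p = 0.0505), Sdc4 (1.98 ± 0.37), Csf1r (1.69 ± 0.40) and Rapgef3 (1.45). On the negative side they were Atp6v1b2 of the vacuolar proton pump (-3.61 ± 0.80), Aff4 (-3.06), Prps1 (-2.74), Atp5md of the ATP synthase (-2.08 ± 0.44), Btbd10 (-1.88), Actr6 (-1.86), Ndufab1 of complex I (-1.79 ± 0.34, limma adjusted p = 0.0505), Lnx1 (-1.60) and Ndufa1 (-1.38 ± 0.32). Low signals enter some of these sizes, such as 3.1, 4.9 and 6.3 for Med14 in controls, and with the pseudocount Med14 had 1.98, Atp6v1b2 -2.73, Aff4 -2.10 and Prps1 -1.78. Leaving out 1 array gave from 0 calls to 141, the latter without control replicate 3 of 120 days. Calls numbered 0 without control replicate 2 or G93A replicate 1 of 120 days, control replicate 1 of 60 days or G93A replicate 3 of 90 days. They numbered 1 without control replicate 1 of 120 days or G93A replicate 2 of 60 days and 2 without G93A replicate 1 or 3 of 60 days. They numbered 7 without G93A replicate 3 of 120 days, 11 without control replicate 2 of 60 days or control replicate 1 of 90 days, and 12 without control replicate 3 of 60 days.

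The microglia and macrophage markers shifted upward at 120 days more than any other list, with a median log2 difference of 1.34 and 19 of 21 members above 0 (camera adjusted p = 1e-07). The shift missed the threshold narrowly with an estimated correlation (adjusted p = 0.0508 with an estimated correlation). Against no change, and not against the other genes, fry gave an adjusted p of 0.004. Over all genes 1 member rose, Lgals3, and 8 rose when adjusted over the list alone: Lgals3, C1qa, Tyrobp, Csf1r, Cst7 (3.82 ± 1.15), Cd52, Lyz2 and P2ry12. The mean levels of Cst7 and P2ry12 lay at percentiles 3 and 21 of all genes, with mean log2 signals of 2.62 and 3.22 in controls. Their sizes thus depend on low signals. The mean list level per array was 0.58 (SD 0.13) in G93A and -0.74 (SD 0.53) in controls, without overlap (exact permutation p = 0.1, n = 3 against 3). The markers of the other glia and of vessels did not pass: astrocytes had a median of -0.14 with a mean of 0, oligodendrocytes 0.23 and endothelium and pericytes 0.32, and centring turned the oligodendrocyte median to -0.02. Gfap (2.25 ± 0.57) rose when adjusted over the astrocyte list alone.

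**Figure D4:**
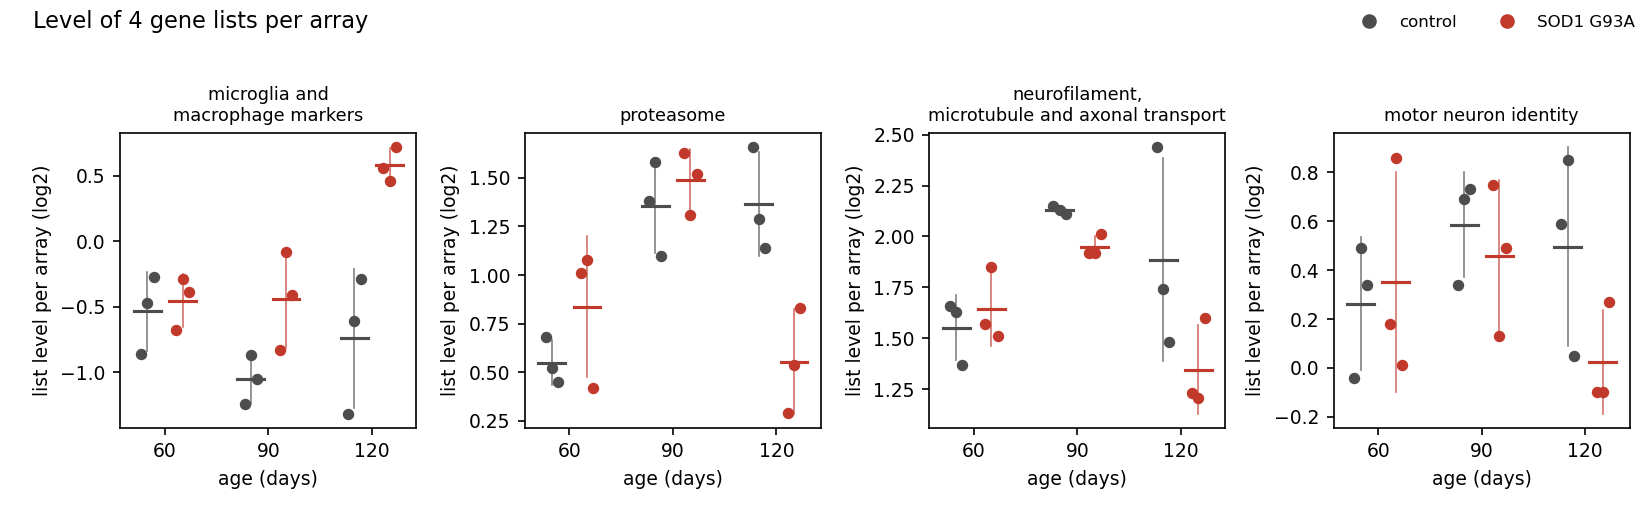
Level of the microglia, proteasome, neurofilament and motor neuron identity lists on each array by age in days and genotype, as the mean log2 level of the members minus the mean over all genes; points are arrays, bars are group means and thin lines 1 SD either way. At 120 days the microglial level averaged 0.58 in G93A and -0.74 in controls, and the proteasome level 0.55 and 1.36.

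The proteasome, chaperone, oxidative phosphorylation, TCA cycle and neurofilament lists shifted downward at 120 days by camera at the preset correlation, and 0 lists passed with an estimated correlation. The sign of these medians held in each scaling alternative. The proteasome list had a median of -0.75 with 35 of 40 members below 0 (adjusted p = 1.4e-06). The call did not hold with an estimated correlation (adjusted p = 0.0982 with an estimated correlation). The adjusted p of fry, which tests against no change and not against other genes, was 0.023. Its members include Psmb4 (-1.68 ± 0.49), Psma5 (-1.03 ± 0.32) and Psmd14 (-0.97), and 0 members passed over all genes or when adjusted over the list alone. The mean proteasome level per array was 0.55 (SD 0.27) in G93A and 1.36 (SD 0.27) in controls (exact permutation p = 0.1, n = 3 against 3). Its median was -0.41 without G93A replicate 1 and -0.48 without control replicate 1 of 120 days. The neurofilament, microtubule and axonal transport list had a median of -0.46 (adjusted p = 2.8e-04, and adjusted p = 0.144 with an estimated correlation). Of its members 0 fell over all genes and 6 when adjusted over the list alone, among them Klc1 (-1.69 ± 0.41), Dync1i1 (-1.19 ± 0.31), Pafah1b1 (-1.28 ± 0.38) and Map2 (-2.35 ± 0.72). The level per array was 1.35 (SD 0.22) in G93A and 1.89 (SD 0.5) in controls, with overlap (exact permutation p = 0.2), and without control replicate 1 of 120 days the median was -0.22.

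Oxidative phosphorylation had a median of -0.27 at 120 days (adjusted p = 6.9e-04, and adjusted p = 0.214 with an estimated correlation), and quantile normalization ended the call (adjusted p = 0.097, the highest over the alternatives). Of its 75 members 0 changed over all genes, while 11 fell and 2 rose when adjusted over the list alone. Those that fell include Atp5md, Ndufa1, Cox7a2l (-1.42 ± 0.35) and Atp5g3 (-1.37 ± 0.36), and those that rose were Cox6a2 (1.51 ± 0.52) and Ndufv1 (0.97 ± 0.33). The TCA cycle list had a median of -0.22 (adjusted p = 0.0022, and adjusted p = 0.144 with an estimated correlation), with 5 members lower when adjusted over the list alone and 0 over all genes: Sdha (-1.38 ± 0.42), Sdhd (-2.98 ± 0.96), Pdhb (-0.91 ± 0.29), Dlst (-1.95) and Mdh1 (-1.51). Heat shock proteins and chaperones had a median of -0.28 (adjusted p = 4.8e-04, and adjusted p = 0.144 with an estimated correlation), and Dnajc5 (-1.52 ± 0.36), Cct4 (-1.54 ± 0.37), Hspd1 (-2.10 ± 0.54), Hspa4 (-1.74) and Hsph1 (-1.27) fell when adjusted over the list alone and 0 over all genes. The level per array overlapped between genotypes for the chaperones (0.76 in G93A and 1.22 in controls, exact permutation p = 0.2), and did not overlap for oxidative phosphorylation (3.1 and 3.49) or the TCA cycle (1.13 and 1.72, exact permutation p = 0.1 for each). The TCA cycle median was -0.47 without G93A replicate 2, -0.43 without G93A replicate 3 or control replicate 2, and -0.37 without control replicate 3 of 120 days. The oxidative phosphorylation median was -0.18 without control replicate 3 of 120 days. Without control replicate 1 of 120 days the chaperone call was lost (adjusted p = 0.071, the highest over the alternatives).

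Translation factors had a median of -0.32 at 120 days (adjusted p = 0.045, and adjusted p = 0.214 with an estimated correlation), with Eif3e (-1.94 ± 0.55) lower and Eif3c (1.65 ± 0.47) higher when adjusted over the list alone and 0 over all genes. The synaptic vesicle list had a median of -0.11 (adjusted p = 0.048, and adjusted p = 0.218 with an estimated correlation), with Atp6v1b2 and Vamp1 (-1.14 ± 0.34) lower when adjusted over the list alone and 0 over all genes. Both calls were lost under quantile normalization, the stricter filter, no trend and array weights, and without G93A replicate 1 or control replicate 1 of 120 days, where adjusted p reached 0.31. The translation call was also lost without G93A replicate 3 of 120 days, and the synaptic call without the least correlated arrays, G93A replicate 2 of 120 days, control replicate 3 of 60 days or control replicate 1 of 90 days. The synaptic median ran from -0.26 to -0.06 with 1 array left out, and from -0.36 to -0.09 over the other alternatives. The level per array overlapped for both lists (exact permutation p = 0.3 and 0.2). The hybridization-control level on the arrays of 120 days differed by -0.01 and the Gapdh ratio by 0.46 between the genotypes, and the median signal was 54.3 in G93A and 43.7 in controls. With the log2 median signal in a model of the level per array, the difference of the members of the proteasome, neurofilament, oxidative phosphorylation, TCA cycle and chaperone lists went from -0.51 to -0.25 (95% interval from -0.51 to 0.02).

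The other 24 lists did not pass camera at 120 days, with adjusted p from 0.063 to 0.90. Motor neuron identity had a median of -0.62 (adjusted p = 0.079), with Chodl (-2.25 ± 0.66) and Nefh (-1.31 ± 0.41) lower when adjusted over the list alone. Axon injury and regeneration genes had a median of 0.75 (adjusted p = 0.075, fry 0.023), with Sprr1a (2.62 ± 0.66) and Atf3 (3.04 ± 0.86) higher when adjusted over the list alone. Glutamate and glycine receptors and calcium handling had -0.27 (fry 0.028), with Gphn (-2.24 ± 0.59) and Glrb (-2.35 ± 0.71) lower when adjusted over the list alone. Oxidative stress defence had -0.06, although Mt1 rose over all genes and, when adjusted over the list alone, Mt2 (1.31 ± 0.40) rose and Gpx4 (-0.98 ± 0.27) fell. Medians were 0.90 for blood cell markers, 0.98 for S to M and -0.04 for G1 to S cell cycle genes, 0.73 for interferon response and MHC class I, -0.44 for interneuron markers, -0.22 for mitochondrial and 0.09 for cytosolic ribosomal proteins, and -0.10 for splicing. They were -0.05 for glycolysis, -0.16 for fatty acid oxidation, -0.19 for cholesterol synthesis, 0.12 for RNA polymerase II and Mediator, -0.08 for endoplasmic reticulum stress, 0.06 for autophagy and lysosome, -0.07 for apoptosis, 0.08 for ion channels and 0.17 for immediate early genes. Centring turned the sign of the medians of cytosolic ribosomal proteins, RNA polymerase II and immediate early genes, and centring and quantile normalization each turned those of autophagy and ion channels. Quantile normalization turned the sign of the astrocyte and glycolysis medians and the test direction of glycolysis. Median and test differed in sign for astrocytes, endoplasmic reticulum stress, G1 to S genes (tests upward) and ion channels (test downward).

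Averaged over the 3 ages, the genotype difference of 9 G93A against 9 control animals passed the test for 2 probe sets. Tyrobp, the signalling adaptor of microglia, rose by 2.25 ± 0.34 (4.76-fold, limma adjusted p = 0.01). The other probe set called, of 1282 at an unadjusted p below 0.05, was a cross-hybridizing one of the lysozyme gene Lyz1 (2.57 ± 0.41, limma adjusted p = 0.0127), and the probe set that represents Lyz1 had -0.17. Other values were Lgals3 (1.92), Vim (1.61), Id2 (1.47) and Ctss (1.08 ± 0.20, limma adjusted p = 0.0805) on the positive side. On the negative side they were Gpx4 (-0.79), Plxdc1 (-1.14), Ighm (-1.16), Limk1 (-1.10) and Lin7b (-0.92), and Nefl had -0.74 ± 0.28 (limma adjusted p = 0.548). Leaving out 1 array gave 0 calls without G93A replicate 2 of 120 days, 1 without G93A replicate 1 of 60 days, G93A replicate 2 of 90 days or control replicate 1 or 3 of 90 days, and 4 without control replicate 1 of 120 days. It gave 6 without G93A replicate 2 of 60 days or control replicate 3 of 120 days, 13 without G93A replicate 1 of 90 days and 16 without control replicate 2 of 90 days.

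By camera 7 lists shifted in the mean over the ages, 5 upward and 2 downward. Microglia and macrophage markers had a median of 0.62 (adjusted p = 9.3e-08) with 18 of 21 members above 0, although at 60 days the list had a median of -0.16 with 7 of 21 above 0 (adjusted p = 0.86), so the mean does not describe a shift at each age. It was the only list called in the mean with an estimated correlation (adjusted p = 0.04999 with an estimated correlation) and by fry (adjusted p = 0.012). Of its members Tyrobp rose over all genes, and Tyrobp, Ctss, Lgals3 and C1qa (0.78) rose when adjusted over the list alone. The others, with adjusted p = 0.301 with an estimated correlation for each except oxidative phosphorylation, were oligodendrocyte markers (0.46, adjusted p = 3.6e-04), cytosolic ribosomal proteins (0.22, adjusted p = 0.0021), the neurofilament list (-0.22, adjusted p = 0.013), astrocyte markers (0.38, adjusted p = 0.019) and blood cell markers (0.49, adjusted p = 0.04). Oxidative phosphorylation had -0.11 (adjusted p = 0.047, and adjusted p = 0.499 with an estimated correlation). Its call was kept in 3 of 12 alternatives and in 6 of 18 fits that leave out 1 array, and the blood cell call in 8 of 12 and 7 of 18. With the hybridization-control level in the model 5 lists were called, 2 upward and 3 downward, of which 3 were among the 7, and the astrocyte median was -0.01. With the Gapdh ratio in the model 8 were called, 3 upward and 5 downward, of which 3 were among the 7. The calls of the oligodendrocyte (median 0.08, test downward), ribosomal (0.03), astrocyte (0.07) and oxidative phosphorylation (-0.06) lists were lost with that ratio, and those of the oligodendrocyte (0.3), astrocyte, blood cell (0.52) and oxidative phosphorylation (-0.09) lists with the hybridization-control level. When adjusted over the list alone, Aqp4 (1.08 ± 0.28) of the astrocyte list and Rpl8 and Rps14 (1.06 each) of the ribosomal list rose, with 0 over all genes. Without control replicate 1 of 90 days, G93A replicate 2 of 120 days or control replicate 2 of 120 days 4 lists were called.

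The genotype difference changed with age for 69 probe sets of 55 genes, and all 69 had a lower difference at 120 than at 60 days. Atp6v1b2 had a difference at 120 minus that at 60 days of -7.68 ± 1.13, Lrrn1 of -5.95 ± 1.03, Etnk1 of -5.79 ± 0.86, Dlst of -5.15 ± 0.93 and Tceal1 of -5.05 ± 0.89 (limma adjusted p of the F test = 0.00481, 0.0177, 0.00481, 0.0249 and 0.0213). Low signals enter these sizes, such as 3.9, 10.6 and 7.5 for Atp6v1b2 in controls at 60 days and 9, 11.2 and 68.9 in G93A at 120 days. With a pseudocount the differences were -5.33 for Atp6v1b2, -4.13 for Lrrn1, -4.86 for Etnk1, -3.85 for Dlst and -3.59 for Tceal1. Calls numbered 0 without the trend, 7 with the hybridization-control level in the model and 144 with the pseudocount, of which 15 were higher. The positive values of the smallest p, which did not pass, were those of Mapkbp1 (4.35), Pard3b (3.76), Ubxn1 (2.93), Csnk2a1 (2.44) and Bicd2 (2.40). Of the 114 calls at 60 days, 46 were among the 69. At 60 days, leaving out G93A replicate 1, 2 or 3 gave 16, 28 or 126 calls in place of 69, and control replicate 1 or 3 gave 140 or 30. At 120 days, leaving out G93A replicate 1 or 2 gave 21 or 44, and control replicate 1, 2 or 3 gave 23, 36 or 250. Without G93A replicate 3 of 90 days there were 38. Across the 16565 probe sets the differences at 60 and 120 days correlated at -0.22, those at 60 and 90 days at 0.21 and those at 90 and 120 days at -0.087, across genes that are not independent replicates. By camera 7 lists differed between 120 and 60 days. The microglial list had 1.22 (adjusted p = 0.0052, and adjusted p = 0.241 with an estimated correlation). The proteasome had -0.95 and the chaperones -0.77 (adjusted p = 2.9e-04, and adjusted p = 0.223 with an estimated correlation for each). The TCA cycle had -0.56 (adjusted p = 0.0036, and adjusted p = 0.223 with an estimated correlation), splicing -0.48 (adjusted p = 0.0052, and adjusted p = 0.241 with an estimated correlation), the neurofilament list -0.46 (adjusted p = 0.015, and adjusted p = 0.257 with an estimated correlation) and translation factors -0.31 (adjusted p = 0.03, and adjusted p = 0.241 with an estimated correlation). The neurofilament call was lost under quantile normalization, with the stricter filter and without the least correlated arrays (median -0.1), and in 3 of 18 fits that leave out 1 array. Its median was -0.29 without control replicate 1 of 120 days and -0.19 without G93A replicate 2 of 120 days. The translation call was lost in 3 of 12 alternatives and in 6 of 18 fits that leave out 1 array, and its median was -0.53 without G93A replicate 3 of 60 days. The proteasome median was -0.54 without G93A replicate 1 of 120 days and -0.57 with the hybridization-control level in the model, that of the TCA cycle -0.95 without control replicate 2 of 60 days and -0.32 with that level. The chaperones had -0.5 without control replicate 1 of 120 days and splicing -0.28 without control replicate 3 of 60 days. By fry 6 lists were called, of which 4 were among the 7.

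Between 60 and 120 days 1112 probe sets changed in controls, 641 higher and 471 lower at 120 days, and 331 in G93A animals, 166 higher and 165 lower. The balance of directions depends on the scaling and the threshold: with each array centred on its median 1396 were higher and 178 lower in controls, and at an unadjusted p below 0.05 by limma 1720 were higher and 2346 lower. In G93A animals these numbers were 134 and 101, and 1102 and 1598. In controls Atp6v1b2 rose by 5.10 ± 0.80, Etnk1 by 4.77 ± 0.61, Ddx5 by 4.59 ± 0.75, Spcs3 by 4.26 ± 0.76 and Enah by 4.24 ± 0.72, with limma adjusted p of 0.000467 for Atp6v1b2 and 8.5e-05 for Etnk1. Zfp189 (-4.78), Prl3c1 (-4.53), Sos1 (-4.47), Padi3 (-4.41) and Cpxm1 (-4.37) fell. Control signals at 120 days were near the floor of 1 for some of these, such as 6.4, 2.4 and 1.9 for Zfp189 and 2.2, 1.2 and 4.2 for Prl3c1, so the sizes and their order are not firm. With a pseudocount the differences were -2.41 for Zfp189, -1.91 for Prl3c1, -2.64 for Sos1, -2.22 for Padi3 and -2.20 for Cpxm1, and 3.48 for Atp6v1b2, 3.89 for Etnk1, 3.61 for Ddx5, 2.62 for Spcs3 and 3.69 for Enah. In 222 of the 1112 calls in controls and 42 of the 331 in G93A the geometric mean of the lower group was below the pseudocount, and 1089 and 317 kept their call with it. In G93A animals Aebp1 rose by 3.96 ± 0.87, Ifi27l2a by 3.52, Plekhh3 by 3.50, the lysosomal protease gene Ctsz by 3.37 ± 0.64, Lgals3 by 3.31 ± 0.72 and Gfap by 3.29 ± 0.57 (limma adjusted p = 0.00551 for Gfap). Dact1 (-4.28), Herpud2 (-4.14), Dnah5 (-3.82), Slc26a3 (-3.80) and Lgr5 (-3.67) fell, with -2.67, -2.42, -1.99, -2.10 and -2.04 for these under the pseudocount. Some of these were not particular to G93A. Control signals of Dact1 were 128.9, 193.6 and 161.3 at 60 days and 5.8, 42.7 and 8.2 at 120 days. In controls Dnah5 and Lgr5 were also lower, and Ifi27l2a higher, at 120 days without overlap. Control signals of the 2 ages overlapped for Herpud2, Slc26a3, Aebp1, Plekhh3, Ctsz, Lgals3 and Gfap. Mbp rose by 1.31 ± 0.38 in controls (limma adjusted p = 0.039) and had a value of 1.03 in G93A (limma adjusted p = 0.166). In both genotypes 67 probe sets changed, 47 higher in both and 17 lower in both, where independent lists would share 6.42 and 4.69. Over all tested probe sets the age differences in controls and in G93A correlated at only 0.11 (rho = 0.1). The overlap thus describes the called probe sets and not the age difference as a whole. In controls 736 probe sets were called without replicate 2 of 60 days, 532 without replicate 3 of 60 days and 603 without replicate 1 of 120 days. In G93A animals 91, 104 and 173 were called without replicate 1, 2 or 3 of 60 days, 209 without replicate 3 of 90 days, and 196 and 102 without replicate 1 or 2 of 120 days. The dates on which arrays were run are not given in the sources used here, so age and array run could not be separated. The hybridization-control level of controls was 12.02 at 60 and 12.63 at 120 days, and of G93A animals 10.35 and 12.62.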

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

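Tests chosen after the result was seen were those of a lower share of motor neurons, of the hybridization-control level and of the median signal for the microglial markers, all 4 tests for the lists that shifted downward at 120 days, and the fits with a covariate.

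The genotype difference itself differed between ages, by a test of the difference, for 69 probe sets. The named genes, with the difference at 120 minus that at 60 days, were Atp6v1b2 (-7.68), Lrrn1 (-5.95), Etnk1 (-5.79), Dlst (-5.15) and Tceal1 (-5.05), and low signals enter these sizes, which were -5.33, -4.13, -4.86, -3.85 and -3.59 with a pseudocount. By camera at the preset correlation 7 lists differed in the same way: microglia and macrophage markers (1.22), proteasome (-0.95), heat shock proteins and chaperones (-0.77), TCA cycle (-0.56), splicing (-0.48), the neurofilament list (-0.46) and translation factors (-0.31), of which 0 passed with an estimated correlation. Control probe sets, which are outside the comparisons, were higher in G93A without overlap in 2 cases. The log2 ratio of the 3' to the 5' Gapdh probe set was higher in G93A by 0.77 at 60 days, and the poly-A controls by 1 at 120 days (3.56 against 2.56), each with an exact permutation p of 0.1 for 3 against 3. The mean log2 poly-A level ran from 2.14 to 3.92 over the 18 arrays, so its difference is 1 between low signals.

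The first pattern is the rise of 111 probe sets in G93A at 60 days, where Etnk1, Id2 and Ptch1 are among the largest. Over the 12 arrays of 90 and 120 days, the mean level of these probe sets fell with the hybridization-control level within groups (r = -0.73, permutation p = 0.044, adjusted over 2 relations 0.088; rho = -0.74, permutation p = 0.045; r = -0.87 without the 2 farthest arrays), and with that level in the model their median difference went from 2.43 (SE 0.48) to 1.81 (SE 0.54), so that 1 call was kept because the difference shrank and its error grew. An array effect that this level reads is therefore a candidate explanation for part of the rise. Signals were scaled per array, so the level is relative to the sample's own signal and does not measure array brightness. Between ages the relation was the opposite of that within groups. Controls at 120 days had a hybridization-control level of 12.63, above the 12.02 at 60 days, and a median level of these probe sets of 8.08 against 5.83. For 3' bias as read from the Gapdh ratio the relation was r = 0.45 (permutation p = 0.27, rho = 0.38, permutation p = 0.32, r = 0.16 without the 2 farthest arrays). The median with the Gapdh ratio in the model was 2.09 (SE 0.52) with 9 calls kept. The 12 arrays were too few to decide, and the beta-actin ratio did not share the Gapdh difference at 60 days, so this bias and the genotype cannot be told apart. An early effect of the transgene stays open and was not tested apart from these.

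The second pattern is the rise of microglia and macrophage markers at 120 days, with Lgals3, Tyrobp and C1qa. A share of motor neurons lost to all other cells alike would raise the markers of each of them. The mean difference of the microglial list (1.41) exceeded that of 46 astrocyte, oligodendrocyte and endothelial markers (0.10) by 1.3 (SE 0.32). This SE is over genes, which were measured on the same animals, and does not measure the spread between animals. The comparison cannot decide on a share lost to microglia or macrophages, which would raise the microglial list alone. An array effect read by the hybridization-control level or the median signal is argued against as the whole cause. The difference of -0.01 in the hybridization-control level, times the slope of the list level on it within groups, gave a shift of 0 (SE 0.07) of the 1.32 observed, which so small a difference keeps near 0. With the median signal in the model 0.98 was left (95% interval from 0.34 to 1.62). RNA of microglia or macrophages taken up with the neurons remains a candidate explanation. A second list of 32 macrophage genes, of which 24 were measured in this material and 0 are in other lists, had a median of 0.83. Of these 20 of 24 were above 0 (camera p = 0.00031, 0.024 with an estimated correlation), while 0 passed when adjusted over the list alone. Its median level lay at percentile 40 of all genes, and it was not modelled on the median signal. At 120 days S to M cell cycle genes (0.98) and blood cell markers (0.90) had medians of similar size without passing camera, while most other lists had lower ones. The size of the median alone is thus not particular to macrophage genes. Mean log2 signals in G93A and controls, each to be set only against the same probe set, were 13.24 and 11.56 for Csf1r, 10.11 and 9.55 for Ctss, 9.96 and 5.96 for Lgals3, 6.65 and 6.28 for Laptm5, and 9.95 and 7.44 for Tyrobp, laser capture of single stained neurons would remove only glia that do not touch them, and a response of motor neurons themselves was not tested.

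The third pattern is the fall of 5 lists at 120 days by camera at the preset correlation, the proteasome, oxidative phosphorylation, TCA cycle, chaperone and neurofilament lists, of which 0 passed with an estimated correlation. Of their 237 members 177 lay under the median of all genes (median -0.35 against 0.07), a count over lists chosen because they fell. An effect read by the hybridization-control level is argued against, since that level differed by -0.01 between the genotypes. Times the slope within groups this gave a shift of 0 (SE 0.08) of the -0.51 in mean list level, which so small a difference keeps near 0. As read from the Gapdh ratio, 3' bias as the whole cause is argued against, since the members stood at -0.45 relative to all genes with that ratio in the model. An effect read by the median signal stays open, and the genotype and that effect cannot be told apart. The slope within groups was -0.82 (SE 0.23), and with the median signal in the model -0.25 was left, with a 95% interval from -0.51 to 0.02. A lower share of motor neurons in the captured material stays open: the 18 motor neuron identity genes had a mean of -0.39 and the members of -0.42, a difference of 0.04 (SE 0.24 over genes). Nefh and Prph are in both sets. Markers of other cells did not rise alike, with a mean of 0.1 for the 46 astrocyte, oligodendrocyte and endothelial markers and 1.41 for the microglial list. This argues against a share lost to all other cells alike, but not against 1 lost to microglia or macrophages. A smaller share and a fall within the neurons, the biological explanation the design offers, therefore cannot be told apart.

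Other splits of the arrays were counted for each result. At 1 age the 6 arrays allow 10 splits, too few for a share under 0.05. At 60 days 1 split, the real one, gave 114 calls and the highest other 8, and for lists 3 splits gave at least the real 3, with 6 the highest other. At 90 days all 10 gave at least the real 0, with 0 the highest other, and for lists 2 gave at least the real 5, with 8 the highest other. At 120 days 1 gave the real 4 calls, with 2 the highest other, and 1 the real 8 lists, with 7 the highest other. Between ages 1 split gave the real 1112 calls in controls and 1 the real 331 in G93A, with 1 the highest other in each. Over all ages 100 splits were drawn. The share was under 0.05 for the mean over ages (2 of 100 splits gave at least the real 2 calls, the highest other 5) and for the change with age (1 of 100 gave the real 69, the highest other 27). These shares were not adjusted over the results, and for the mean over ages another split gave more calls than the real one. Chance was thus made less likely and not excluded. The share was not under 0.05 for lists in the mean (7 of 100 gave at least the real 7, the highest other 9) or for lists that differ between 120 and 60 days (16 of 100 gave at least the real 7, the highest other 11).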

How the results depend on the processing

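The fits with a covariate and the fit without the least correlated array of each age were chosen after seeing the data. Where a result changed with a setting, the cause was not tested unless stated.

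At 120 days the microglial, proteasome, neurofilament, TCA cycle and chaperone lists kept their call and direction in 12 of 12 alternatives other than leaving out an array and the other list tests, with medians from 1.01 to 2.17 for the microglial list and from -1.01 to -0.51 for the proteasome; with 1 array left out they ran from 0.96 to 1.48 and from -0.89 to -0.41, and those of the neurofilament and TCA cycle lists from -0.62 to -0.22 and from -0.47 to -0.22. Over the 160 list results, 4832 values were computed: 4610 kept their side of the threshold, 154 lost and 65 gained the call, and 3 of called lists turned direction, all with the Gapdh ratio in the model: oligodendrocyte markers at 90 days (-0.12), interneuron markers at 90 days (-0.23) and oligodendrocyte markers in the mean over ages (median 0.08, test downward). The test direction also turned in 216 values of lists that had not been called. Over 494 gene results, 14308 of 14871 values kept their side, 402 lost and 161 gained the call, and 0 values of called genes turned direction, while 59 values of genes not called did. Tyrobp in the mean over ages kept its call in 27 of 30 settings and Etnk1 at 60 days in 29 of 30, the exception being the hybridization-control covariate (2.72, adjusted p = 0.14, range over the alternatives 0.00067 to 0.14).

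Quantile normalization gave 1 call at 120 days, 4 in the mean over ages, 0 lists at 60 days and 5 at 120 days. Median centring gave 0 calls at 120 days, where limma had 2022 probe sets at an unadjusted p below 0.05 before centring, and 221 (1 higher, 220 lower) for the change with age; in controls it gave 1574 calls between ages, 1396 higher and 178 lower, beside 641 and 471. Without the filter 13 lists were called at 120 days. The stricter filter gave 1 call in the mean, 0 lists at 60 days and 3 at 90 days, with fewer genes in the lists. The pseudocount gave 23 calls at 120 days (15 higher, 8 lower, 3 shared with the 4), 11 in the mean and 144 for the change with age (15 higher, 129 lower). Without the trend there were 20 calls at 60 days, 1 at 90 days, 1 at 120 days, 1 in the mean, 0 for the change with age, 549 between ages in controls, 31 in G93A, 0 lists at 60 days and 3 at 90 days. Array weights gave 1 call at 120 days, 667 between ages in controls, 1 list at 60 days and 2 at 90 days.

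With the hybridization-control level in the model there were 1 call at 60 days, 53 at 120 days (19 higher, 34 lower, 4 shared with the 4), 1 in the mean, 7 for the change with age, 1884 between ages in controls, 26 in G93A (21 higher, 5 lower), 0 lists at 60 days and 1 at 90 days. With the Gapdh ratio there were 10 calls at 60 days, 8 at 120 days, 0 in the mean (1282 at an unadjusted p below 0.05 by limma without it), 143 between ages in controls (108 higher, 35 lower), 208 in G93A, 0 lists at 60 days, 1 at 90 days and 13 at 120 days. Without the least correlated arrays (control replicate 3 of 60 days, control replicate 1 of 90 days, G93A replicate 2 of 120 days) there were 26 calls at 60 days, 7 at 120 days (0 higher, 7 lower), 1 in the mean, 24 for the change with age, 523 between ages in controls, 146 in G93A, 0 lists at 90 days and 4 in the mean. With only the arrays of the ages compared, and so fewer degrees of freedom, there were 35 calls at 60 days, 0 at 120 days, 740 between ages in controls and 132 in G93A.

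With an estimated correlation 0 lists were called at 60, 90 and 120 days and for the difference between 120 and 60 days, and 1 in the mean. By fry 0 lists were called at 60 and 90 days, 4 at 120 days (2 shared with the 8), 1 in the mean and 6 for the difference between 120 and 60 days (4 shared with the 7).

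The sample numbers did not pair the arrays: deviations of G93A and control arrays with the same number correlated at -0.12 to 0.06, and not every array correlated best with its own number. With the replicate block there were 7 calls at 120 days (4 higher, 3 lower, 3 shared with the 4) and 4 in the mean, and it moved no other count by over 1.5 times. With the animal number series at 90 days as a block, 0 probe sets and 5 lists were called at 90 days and 63 probe sets for the change with age.

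Leaving out each array in turn gave 7 (G93A replicate 1 of 60 days) to 267 calls (control replicate 1 of 60 days) at 60 days, 0 to 2 (control replicate 2 of 90 days) at 90 days, 0 to 141 (control replicate 3 of 120 days) at 120 days, 0 (G93A replicate 2 of 120 days) to 16 (control replicate 2 of 90 days) in the mean, and 16 (G93A replicate 1 of 60 days) to 250 (control replicate 3 of 120 days) for the change with age. Between ages it gave 532 (replicate 3 of 60 days) to 1156 calls in controls and 91 (replicate 1 of 60 days) to 483 in G93A. Lists called ranged from 0 to 5 at 60 days, 0 to 6 at 90 days, 6 to 10 at 120 days, 4 to 8 in the mean and 5 to 8 for the difference between 120 and 60 days. Lgals3 at 120 days had 2.83 without control replicate 1. The number of arrays and signals close to background, as for Galnt2, limit these counts: of the 114 calls at 60 days 23 had a geometric mean of the lower group below the pseudocount, and 97 kept their call with it.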

Other observations

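The 18S rRNA level differed between G93A and control arrays by -0.88 at 60 days, -1.33 at 90 days and 0.54 at 120 days on the log2 scale, with exact permutation p of 0.2, 0.1 and 0.3 for 3 against 3. The first 3 principal components of the tested probe sets held 15.5%, 13.6% and 6.87% of the variance. The mean correlation of an array with the other 17 was lowest, at 0.613, for control replicate 3 of 60 days.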
